A study of Mus musculus with 1627 samples.

How the data were processed

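Single Foxp3-reporter Tregs from the spleen and injured muscle of mice were profiled with inDrops, in which each droplet holds a cell and a barcoded primer that starts at the poly(A) tail, so counts come from the 3' side of transcripts. Per the labels' protocols, live cells carrying the T cell receptor, CD4 and the reporter were sorted by flow cytometry, spleens were dissociated mechanically and muscles digested with collagenase and dispase. The authors deposited a table of raw UMI counts per gene and cell, with 23725 genes and 1627 cells; the submitters' processing notes name the mm10 genome build, TopHat2 and SAMtools without versions. Gene annotation, strand setting, UMI collapsing and cell filter are not given in the sources used here. The table's counts summed to 98.7% of the UMIs the labels state for spleen cells and 98.8% for the cells of each muscle library. Per the labels, each deposited cell belongs to 1 of 3 libraries, 1 of spleen and 2 of muscle, and cells were assigned to libraries by those labels. Every cell was kept, with at least 756 UMIs, and 14543 genes had at least 1 UMI. The table has no rows for mitochondrially encoded genes or for the T cell receptor constant genes, so these were not analysed here.

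Cells are not replicates, and the labels name no animal, so UMIs were summed per library and scaled to CPM of the library sum. The value of 1 UMI was 1.02 CPM in spleen, 0.65 in muscle library 1 and 0.52 in muscle library 2. Folds of each muscle library over spleen carry exact conditional binomial (Clopper-Pearson) 95% intervals, single levels exact Poisson intervals and shares of cells exact binomial intervals. Where a library had 0 UMIs the floor of 3 counts took its place, so the fold rests on that floor and its exact interval can reach lower. UMIs cluster within cells, which these intervals leave out: Foxp3, for example, averaged 2.97 UMIs in each of the 122 spleen cells where it was seen. A gene was called higher or lower in muscle when both muscle libraries differed from spleen by at least 2-fold in the same direction, among genes with at least 50 UMIs over the 3 libraries. This rule of size is no test. On simulated counts 7568 genes passed the UMI minimum, and 200 genes had been altered, 50 at each size. Of the raised genes that passed, the rule recovered 49 of 50 at 3-fold and 50 of 50 at 5-fold. Of the lowered genes that passed, it recovered 35 of 38 at 3-fold and 25 of 25 at 5-fold. The minimum thus removed lowered genes but no raised ones, so recovery among all lowered genes was smaller. The rule called 28 of 7405 unaltered genes, and the simulation held counting noise alone.

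The rule for named genes, the 28 gene lists, the cluster markers and most alternatives were set before the data were examined. Named are the 12 genes higher and 12 lower in muscle with the largest smaller log2 fold over the muscle libraries, at least 100 UMIs and a smaller fold that exceeds the difference between the muscle libraries, leaving out ribosomal protein genes, predicted genes and receptor segments. Up to 4 members of each list with 3 or more measured genes, the check genes Foxp3, Cd4, Cd3e, Trbc2 and Xist, and the 5 genes each way with the largest fold between the muscle libraries complete the rule. Some genes that the rule or a test names are not reported here. A list's median of the mean of the 2 log2 folds was placed among 10000 random lists of the same size matched on expression deciles, as a description of these libraries. The mitochondrial list had 0 measured genes. Gene coordinates come from GENCODE M21 on GRCm38, matched by symbol; 96.2% of the table's symbols occur there, and the table's own annotation is not known.

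For shares of cells, each cell was thinned without replacement to 1000 UMIs with seed 1. For clusters, genes seen in at least 3 cells were scaled to 10000 counts per cell and log-transformed, the 1500 most variable genes entered 20 principal components, and 15 neighbours with Leiden resolution 0.8 gave the groups. A cluster was named only from at least 3 of the fixed markers among its 10 leading genes. No doublet caller was run, since the sort holds 1 cell type; 0 spleen cells, 12 cells of muscle library 1 and 7 of muscle library 2 exceeded 3 times their library's median UMI count and stayed in. Alternatives covered the scaling (edgeR TMM factors, DESeq2 size factors, totals without ribosomal protein genes), the UMI minimum, the fold, equal weight per cell, thinned cells, each muscle library alone, the thinning depth and the clustering settings. The edgeR and DESeq2 packages supplied scaling factors only. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scanpy 1.11.5, igraph 0.11.9 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.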

Results

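Foxp3-expressing regulatory T cells (Tregs) restrain immune responses, and those that gather in injured muscle take part in its repair. Single Tregs were sorted from the spleen and the injured skeletal muscle of male mice aged 8 months, 4 days after cardiotoxin, a snake venom toxin that destroys muscle fibres. The mice carried a green fluorescent reporter under Foxp3, and the cells were profiled with inDrops, a droplet method that tags each captured mRNA with a unique molecular identifier (UMI). The design asks how Tregs of the injured muscle differ from those of the spleen at the same time. The spleen was represented by 1 library of 259 cells, and the muscle by 2 libraries of 674 and 694 cells, called muscle library 1 and muscle library 2 here. Counts summed to 982570 UMIs in spleen, 1533277 in muscle library 1 and 1916496 in muscle library 2. The median cell held 3541 UMIs in spleen, 1976 in muscle library 1 and 2488 in muscle library 2, and the full range over all cells was 756 to 9628. Sequencing depth per molecule also differed, with a median of 55.8 reads per UMI in spleen, 24.7 in muscle library 1 and 45.3 in muscle library 2. The labels name no animal, so each tissue counts as 1 sample, no test between tissues was made, and no p-value is given. All intervals are exact 95% intervals that cover counting error only.

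The sorted identity of the cells was visible in every library. Foxp3, the transcription factor that defines Tregs, stood at 368 CPM (counts scaled to a common library total) in spleen (exact Poisson interval 331 to 408), 554 in muscle library 1 and 552 in muscle library 2. Cd4 reached 384, 554 and 598 CPM in the same order, and Cd3e, a subunit of the T cell receptor complex, 221, 222 and 223 CPM. Of the 11 measured T cell identity genes, 0 differed by 2-fold in both muscle libraries, and their median log2 fold was 0.05, a sign that turned with other scalings, to -0.02 with DESeq2 size factors and -0.10 without ribosomal protein genes in the total. Cd28 was the member with the largest difference downwards, at 639 CPM in spleen, 488 in muscle library 1 and 377 in muscle library 2, while Cd2 stood at 598, 788 and 903 CPM and Thy1 at 557, 699 and 727 CPM. Xist, which female cells express strongly, was near the detection limit with 15, 11 and 33 UMIs, in libraries labelled male. Trbc2, a T cell receptor constant gene, has no row in the table used here.

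Transcripts of other cell types were scarce. Of the 17 myeloid genes only Ctss and Cst3, which T cells also express, reached 50 UMIs, and 0 of these 2 differed by 2-fold. Lyz2, an abundant macrophage transcript, gave 0 UMIs in spleen, 3 in muscle library 1 and 6 in muscle library 2. Among B cell genes 3 were measured, of which Cd74 was 2.04-fold (1.57 to 2.69) and 2.07-fold (1.6 to 2.71) higher in the 2 muscle libraries. H2-Aa had 0 spleen UMIs and was 6.62-fold and 6.32-fold higher with the floor of 3 counts in spleen. With each of the 3 other scalings (TMM factors, DESeq2 size factors, totals without ribosomal protein genes) Cd74 fell below the rule, leaving 1 higher gene. Cd74 and H2-Aa encode proteins of MHC class II antigen presentation, whereas the B cell receptor gene Cd79b stood at 13.2, 13.0 and 11.5 CPM. The CD8 and NK cell list had 3 measured genes and 0 past 2-fold: Ccl5 stood at 119, 190 and 151 CPM, Cd8b1 at 52.9, 37.8 and 65.7 CPM, and Nkg7 at 23.4, 33.9 and 15.1 CPM. The muscle fibre, fibroblast, endothelial, erythroid and platelet, and conventional CD4 lists had 1 measured gene each and 0 past 2-fold.

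Muscle Tregs differed from spleen Tregs across many genes in both directions. Among 7617 genes with at least 50 UMIs, 569 were at least 2-fold higher in both muscle libraries than in spleen and 263 at least 2-fold lower. Genes higher in muscle took 2.80% of spleen UMIs but 8.54% and 8.50% of the UMIs of the 2 muscle libraries. Genes lower in muscle took 4.14% of spleen UMIs against 1.59% and 1.57%. The direction of these shares follows from how the genes were chosen, so they describe size only. Lmna, which encodes the nuclear lamina proteins lamin A and C, was 22.0-fold higher in muscle library 1 (14.8 to 34.2) and 22.9-fold higher in muscle library 2 (15.4 to 35.6), at 560 and 583 CPM against 25.4 in spleen. Mmp9, a matrix-degrading protease, was 13.7-fold (6.11 to 37.9) and 14.8-fold (6.66 to 40.8) higher.

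Further genes higher in muscle had between 0 and 30 spleen UMIs. Tff1, a secreted trefoil factor, had 0 UMIs in spleen against 91 and 126 in the muscle libraries. With the floor of 3 counts in spleen it was 19.4-fold and 21.5-fold higher. Ccr1, a chemokine receptor, had 1 spleen UMI and was 67.3-fold higher in muscle library 1 (11.8 to 2683) and 42.0-fold higher in muscle library 2 (7.34 to 1681). Ifitm3, an interferon-induced antiviral membrane protein, and Slc52a3, a riboflavin transporter, also had 1 spleen UMI each, and their folds were 50.6 and 41.5 for Ifitm3 (lower bounds 8.83 and 7.25) and 23.7 and 32.8 for Slc52a3 (lower bounds 4.00 and 5.68). The cysteine protease inhibitor genes Ctla2a and Ctla2b were higher by 15.6-fold and 17.0-fold for Ctla2a and by 55.3-fold and 42.7-fold for Ctla2b, the latter from 3 spleen UMIs (18.7 to 270.0 and 14.5 to 209). These 2 are close relatives that may share reads, so their separate values are uncertain. Rnase4 was 14.2-fold and 15.3-fold higher, Rsad2 14.7-fold and 12.3-fold, and Ifit3 13.9-fold and 11.2-fold. Rnase4 overlaps Ang on the same strand, and Ifit3 has the close copy Ifit3b, so reads of these genes may be shared as well.

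The genes lower in muscle included regulators of resting lymphocytes. Tcf7, a transcription factor of naive and memory T cells, stood at 128 CPM in spleen, 8.48 in muscle library 1 and 2.61 in muscle library 2, which is 15.1-fold (8.53 to 29.2) and 49.2-fold (20.5 to 154) lower. Ccr7, the chemokine receptor that guides T cells to lymph nodes, was 9.75-fold (7.60 to 12.7) and 8.31-fold (6.72 to 10.4) lower, from 464 CPM in spleen. Bach2, a repressor of effector genes, was 9.49-fold and 8.90-fold lower, and Bcl2, a survival factor, 7.47-fold and 8.45-fold lower. Tbc1d4 was 15.1-fold and 37.7-fold lower, Nsg2 13.6-fold and 33.9-fold, Pdlim1 15.6-fold and 10.6-fold, Itm2a 10.3-fold and 10.9-fold, Ift80 7.07-fold and 7.55-fold, Evl 10.3-fold and 6.83-fold, Actn1 6.38-fold and 6.75-fold, and Lrig1 9.53-fold and 5.95-fold.

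On the GRCm38 (mm10) assembly with the GENCODE M21 annotation, Lmna spans 88480147 to 88509956 of chromosome 3 and Mmp9 164940780 to 164955850 of chromosome 2. Ccr1 spans 123962124 to 123968692 of chromosome 9. Ctla2b spans 60895350 to 60897447 and Ctla2a 60934155 to 60936625 of chromosome 13. Tff1 spans 31161395 to 31165277 of chromosome 17, where the predicted gene Gm15318 lies on the opposite strand. Ctla2a and Ctla2b both overlap the predicted genes Gm49391 and Gm49393 on the same strand, and Ctla2b also Gm49392. Tcf7 spans 52252371 to 52283014 and Ccr7 99144196 to 99155077, both on chromosome 11, and Bach2 spans 32238804 to 32586108 of chromosome 4. On the same strand Tcf7 overlaps Gm26551, and Bach2 overlaps Bach2it1 and Gm24371; on the opposite strand Tcf7 overlaps A630014C17Rik and Bach2 overlaps Bach2os. Each gene given with its span is annotated as protein-coding, and the counts cover the gene as a whole without naming exons.

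In comparison with the tissue difference, the spread between the muscle libraries was smaller, though they are not measured alike. The spleen library held the fewest UMIs, so folds over it carry more counting noise. With 1 spleen library, the spread within spleen is not known. The standard deviation of log2 folds over genes was 0.50 between the muscle libraries, 0.84 for muscle library 1 over spleen and 0.85 for muscle library 2 over spleen. Since both muscle libraries are set against the same spleen library, their calls overlap by chance. Simulated unchanged libraries of the same depth, with counting noise alone, gave 26 higher and 3 lower genes, and independent lists would share 86.2 higher and 36.5 lower genes. Neither covers overlap from deviations of the spleen library beyond counting noise, which both folds share, so the full overlap by chance is not known. Either muscle library alone gave 788 or 833 higher genes and 525 or 530 lower genes. Ribosomal protein genes took 21.0% of spleen UMIs but 12.6% and 13.0% of muscle UMIs. Leaving them out of the scaling shifted the median log2 fold of all genes. It went from 0.06 to -0.09 in muscle library 1 and from 0.08 to -0.06 in muscle library 2. This scaling moved the split from 569 higher and 263 lower to 439 and 394, or from 68.4% to 52.7% higher. The split also moved with the UMI minimum, to 62.0% higher with at least 10 UMIs and 76.2% with at least 200.

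**Figure D1:**
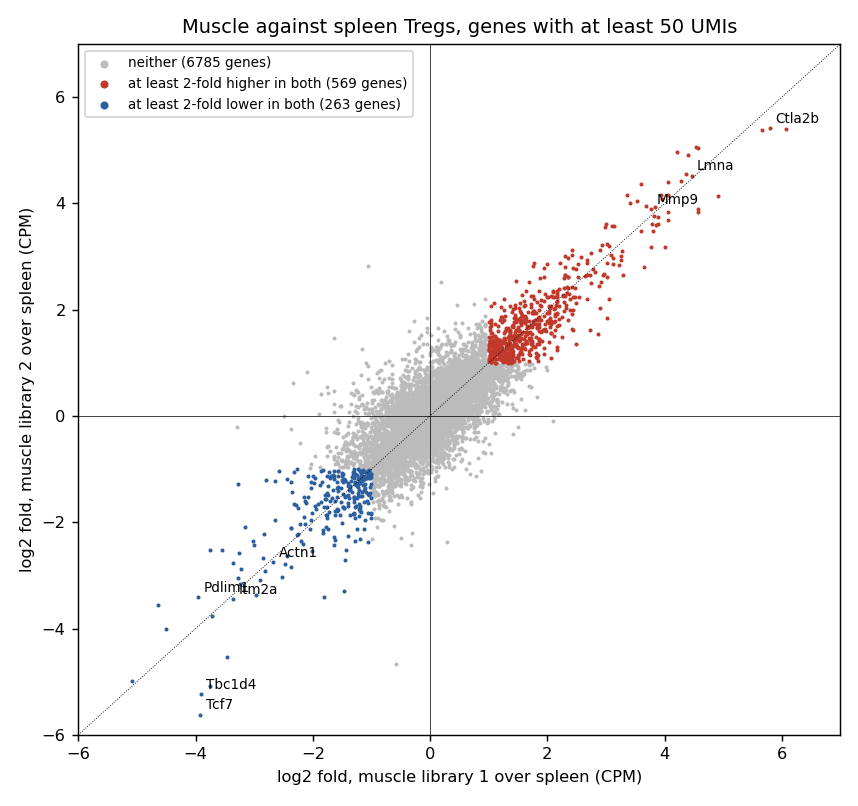
Log2 fold of each gene in muscle library 1 (horizontal axis) and muscle library 2 (vertical axis) over the spleen library, for 7617 genes with at least 50 UMIs; red points are the 569 genes at least 2-fold higher in both muscle libraries, blue points the 263 genes at least 2-fold lower, and the dotted line marks equal folds. Lmna, at 22.0-fold and 22.9-fold, lies among the largest differences upwards, and Tcf7, at 15.1-fold and 49.2-fold lower, among the largest downwards.

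Gene lists fixed before the data were examined moved unevenly between the tissues. Of 20 measured tissue Treg genes, 12 were at least 2-fold higher in both muscle libraries and 0 lower, with a median log2 fold of 1.53, above all of 10000 random lists matched on expression. Besides Ccr1, these included Il1rl1, the receptor for interleukin 33, which was 9.70-fold (6.24 to 15.9) and 8.59-fold (5.53 to 14.1) higher, Itgae at 7.61-fold and 9.29-fold, and Havcr2 at 7.37-fold and 5.45-fold. Klrg1, named after its values were seen, was 2.85-fold and 4.09-fold higher. Areg, the growth factor amphiregulin, and Il10, both also named after their values were seen, stayed below the 2-fold rule at 1.59-fold and 1.31-fold for Areg and 1.72-fold and 1.5-fold for Il10. Of 14 effector and memory T cell genes, 10 were higher and 0 lower, with a median log2 fold of 1.3: Vim was 4.79-fold and 4.80-fold higher, S100a4 4.50-fold in both, Id2 4.14-fold and 3.59-fold, and S100a6 3.26-fold and 3.0-fold.

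Suppressive molecules and receptors were higher in muscle for 9 of 17 measured members, lower for 1 and neither for 7, with a median log2 fold of 1.2. Gzmb, the cytotoxic protease granzyme B, stood at 273 CPM in spleen against 2374 and 2148 CPM, 8.70-fold (7.69 to 9.89) and 7.88-fold (6.96 to 8.95) higher. Fgl2 was 9.76-fold and 6.31-fold higher, and Entpd1, the ectoenzyme CD39, 5.61-fold and 4.36-fold higher. Ctla4 and Icos, chosen after their values were seen, were 3.21-fold and 2.32-fold higher for Ctla4 and 2.86-fold and 2.65-fold higher for Icos. Lrrc32, which anchors latent TGF beta on the cell surface, went the other way at 4.77-fold (3.61 to 6.39) and 3.33-fold (2.65 to 4.21) lower. The 10 Treg identity genes were divided, with 3 higher, 2 lower and 5 neither, and a median log2 fold of 0.51. Socs2 was 3.64-fold and 3.03-fold higher, Capg 2.89-fold and 3.42-fold, and Ikzf4 2.84-fold and 2.88-fold, while Gpr83, an orphan receptor, was 22.6-fold (8.38 to 85.8) and 16.2-fold (7.37 to 42.0) lower. Foxp3 itself was 1.5-fold higher in both muscle libraries (1.33 to 1.71 and 1.33 to 1.69).

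The resting lymphoid list moved the other way. Of 12 measured members, 0 were higher in muscle and 6 lower, with a median log2 fold of -1.32, below all of 10000 random lists. Tcf7, Bach2, Ccr7 and Bcl2, described above, led the list.

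Genes linked to helper T cell programs were higher in part. Of 5 Th1-linked genes, 3 were higher and 0 lower, with a median log2 fold of 1.70: among the higher ones, the chemokine receptor Cxcr3 was 3.33-fold and 3.81-fold higher and the transcription factor Tbx21 4.49-fold and 2.36-fold, while Stat4 stood at 1.46-fold and 1.2-fold. Of 5 Th2-linked genes, 2 were higher and 0 lower, with a median log2 fold of 0.80: Il1rl1, as above, and Ccr4 at 2.04-fold and 3.08-fold, whereas Gata3 at 2.04-fold and 1.49-fold and Il4ra at 1.40-fold and 1.69-fold missed the rule. With each of the 3 other scalings Ccr4 also missed it, leaving 1 higher gene. The Th17-linked list had only 2 measured genes, of which 1 was higher. Of 3 follicular Treg-linked genes, 1 was lower and 0 higher: Bcl6 was 2.57-fold and 2.48-fold lower, Pdcd1 stood at 69.1 and 91.8 CPM against 34.6 in spleen, and Tox at 140 and 101 CPM against 178. Of 13 homing and adhesion genes, 4 were higher, or 3 with each of the other scalings, and 2 lower. Ccr6 was 3.51-fold higher in both muscle libraries, while Ccr9, the gut-homing chemokine receptor, was 8.03-fold (3.52 to 21.4) and 5.40-fold (2.80 to 11.1) lower.

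Interferon response genes were higher in muscle. Of 17 measured members, 10 were higher and 0 lower, with a median log2 fold of 1.13, above all of 10000 random lists; with TMM factors 9 were higher, with DESeq2 size factors 8 and without ribosomal protein genes in the total 7. Besides Rsad2 and Ifit3, Irf7, a transcription factor that amplifies interferon production, was 4.35-fold (2.79 to 7.06) and 4.73-fold (3.07 to 7.62) higher and Usp18 3.98-fold and 3.83-fold higher. Of 14 NF-kB-linked genes, 3 were higher and 1 lower, with a median log2 fold of 0.61. Nfkb2 was 5.95-fold and 7.98-fold higher, Traf1 2.03-fold and 2.65-fold, and Nfkbia, the inhibitor of NF-kB, 2.06-fold and 2.02-fold, while Rel was 2.28-fold and 2.06-fold lower. Traf1 and Nfkbia lay at the threshold and fell below it with each of the 3 other scalings, which left 1 higher gene, Nfkb2.

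Immediate early genes, which respond within minutes to stimulation or handling, were higher in part, in a muscle sample that was digested with enzymes while the spleen was dissociated mechanically. Of 16 measured immediate early genes, 4 were higher and 1 lower, with a median log2 fold of 0.49 at percentile 98.4 of the random lists. Fosb was 8.05-fold and 7.38-fold higher, Jund 3.25-fold and 2.97-fold, and Zfp36, which destabilises inflammatory mRNAs, 2.70-fold and 2.56-fold, while Egr2 was 3.36-fold and 4.37-fold lower. Of 11 heat shock genes, 0 were higher and 1 lower, with a median log2 fold of -0.56. Hsph1 was 2.39-fold and 3.26-fold lower, Hspe1 stood at 449 CPM in spleen against 255 and 216, and Dnaja1 at 692 CPM against 431 and 439. Hspa1a, a close copy of Hspa1b, had 7, 11 and 33 UMIs.

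Metabolic and cell cycle lists had few members past the rule. Of 14 glycolysis genes, 3 were higher and 0 lower, with a median log2 fold of 0.59 at percentile 99.6 of the random lists: Tpi1 was 2.55-fold and 2.85-fold higher, Pkm 2.21-fold and 2.53-fold, and Aldoa 2.07-fold and 2.50-fold, while Pgam1 stood at 1.62-fold and 2.07-fold. With TMM factors or DESeq2 size factors 2 genes of this list were higher, without Aldoa, and without ribosomal protein genes in the total 1. Of 18 oxidative phosphorylation genes, 0 passed the rule either way, and Ndufa4 came closest at 2.09-fold and 1.72-fold, ahead of Cox7a2 at 1.51-fold and 1.28-fold. Of 14 S phase genes 1 was higher, Tipin at 2.75-fold (1.18 to 7.41) and 2.49-fold (1.09 to 6.66), and Mcm5, Mcm2 and Dut lay between 1.48-fold and 2.34-fold, though the mean log2 fold of Mcm2 turned from 0.71 to -0.43 in cells thinned to 1000 UMIs. Of 10 G2 and M phase genes 1 was higher, Cenpa at 2.06-fold and 2.35-fold, and 0 with each of the 3 other scalings, while Birc5 stood at 25.4, 20.2 and 4.70 CPM, Top2a at 28.5, 60.7 and 32.4 CPM, and Cks2 at 45.8, 86.7 and 52.2 CPM.

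**Figure D2:**
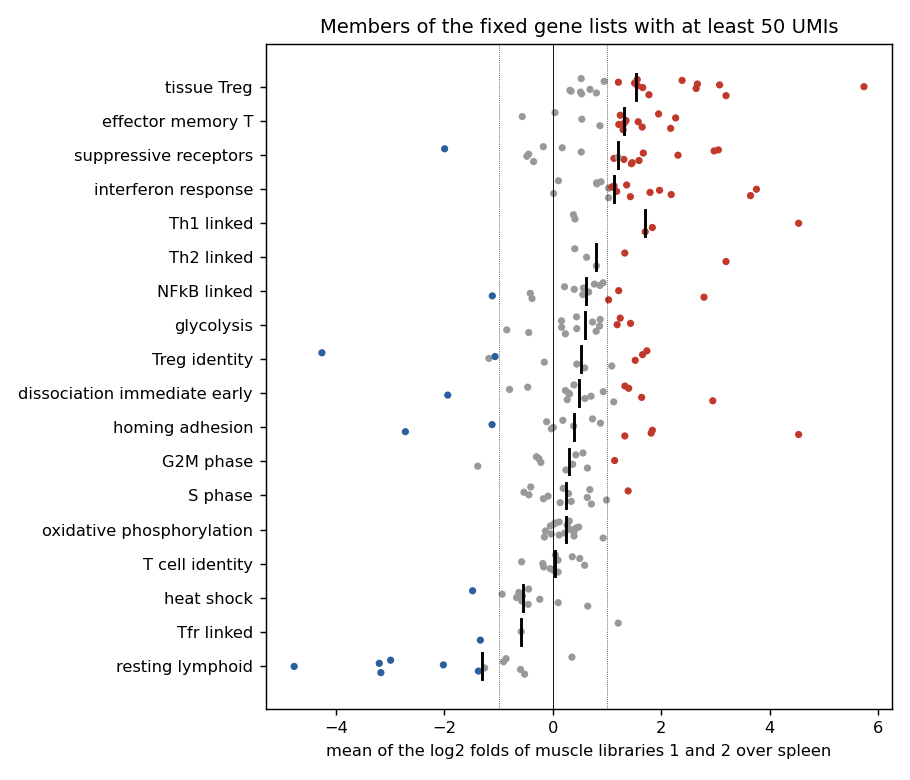
Each point is 1 gene of a fixed list with at least 50 UMIs, placed by the mean of its log2 folds in muscle libraries 1 and 2 over spleen; red genes were at least 2-fold higher in both muscle libraries, blue genes at least 2-fold lower, and grey genes neither, with list medians as black bars and 2-fold differences as dotted lines. The median of the tissue Treg list lies at 1.53 and that of the resting lymphoid list at -1.32.

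The muscle libraries also differed from each other, which shows how far 2 libraries of 1 tissue can stand apart. Of the 7617 genes, 240 were at least 2-fold higher in muscle library 2 and 136 at least 2-fold lower. Scn2b, a sodium channel subunit, stood at 67.8 CPM in muscle library 2 against 7.83 in muscle library 1, Tceanc at 38.6 against 4.57, Tmem176a at 52.7 against 10.4, Slx1b at 68.9 against 14.3 and Lrrc8a at 38.6 against 8.48. In the other direction Rfx5 stood at 9.91 CPM against 34.6, the interferon-induced gene Cmpk2 at 20.3 against 66.5, Tcf7 at 2.61 against 8.48, the clock gene Cry1 at 36.0 against 111, and Asun at 25 against 76.3. Foxp3, Cd4 and Cd3e differed little, at 552 against 554 CPM, 598 against 554 and 223 against 222, and Xist stood at 17.2 against 7.17 CPM. Simulated libraries of equal composition gave 35 of 7568 genes with a 2-fold difference in either direction, against 376 of 7617 observed. Chi-square over its degree of freedom averaged 5.04 per gene, where counting noise alone gives about 1, and its median was 1.59, where counting noise alone gives 0.45. It averaged 17.0 for muscle library 1 against spleen and 18.7 for muscle library 2 against spleen. UMIs cluster within cells, which neither the simulation nor the chi-square includes, so part of each excess may come from that.

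At the level of single cells, the same genes were found in different shares of cells. After every cell was thinned to 1000 UMIs, Gzmb was detected in 5.02% of spleen cells (2.70 to 8.43), 46.1% of muscle library 1 cells (42.3 to 50.1) and 42.5% of muscle library 2 cells (38.8 to 46.3). Il1rl1 was detected in 2.70% of spleen cells (1.09 to 5.49), 14.8% (12.2 to 17.8) and 13.5% (11.1 to 16.3), and Lmna in 1.16%, 32.3% and 30.0%. Klrg1, chosen after its values were seen, was found in 6.95%, 29.5% and 32.5% of cells. Ccr7 was found in 22.8% of spleen cells (17.8 to 28.4) but 2.47% (1.42 to 3.98) and 2.91% (1.79 to 4.46) of muscle cells, and Foxp3 in 24.3% (19.2 to 30.0), 38.9% (35.1 to 42.8) and 35.1% (31.5 to 38.8). Without thinning the shares in spleen, muscle library 1 and muscle library 2 were 5.41%, 52.5% and 51.2% for Gzmb, 4.25%, 22.3% and 22.2% for Il1rl1, 36.7%, 5.34% and 4.47% for Ccr7, and 47.1%, 56.5% and 56.1% for Foxp3. As background, Lyz2 was detected after thinning in 0 of 259 spleen cells (exact interval 0 to 1.41% of cells with a UMI, where 3 cells would be 1.16%), in 2 of 648 cells of muscle library 1 and in 1 of 687 cells of muscle library 2. Over 17 myeloid genes the median share was 0% in spleen, 0% in muscle library 1 and 0.15% in muscle library 2. The largest was that of Ctss, which T cells also express, at 23.9%, 33.3% and 23.9%. Over 8 B cell genes the median was 0%, 0.23% and 0.15%, and the largest share was that of Cd74 at 5.79%, 12.5% and 9.46%. Thinning left out 26 shallower cells of muscle library 1, 7 of muscle library 2 and 0 of spleen.

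The summed share of tissue Treg and effector memory genes differed across most cells rather than in a few. A change within cells and a different mix of cell states cannot be told apart from such shares. Tissue Treg and effector memory genes together made up a median of 0.50% of a spleen cell's UMIs (quartiles 0.20 and 1.2), against 2.50% in muscle library 1 (1.80 and 3.10) and 2.40% in muscle library 2 (1.70 and 3.10). On their own, effector memory genes had medians of 0.30% in spleen against 1.75% and 1.80% in the muscle libraries. Tissue Treg genes had medians of 0.10% in spleen against 0.50% in both muscle libraries. For the combined share, 4.63% (2.42 to 7.95) of spleen cells lay above the median of muscle library 1 and 5.41% (2.99 to 8.90) above that of muscle library 2. Conversely 1.23% (0.53 to 2.42) of cells of muscle library 1 and 0.87% (0.32 to 1.89) of muscle library 2 lay below the spleen median. Resting lymphoid genes overlapped more: their median share was 0.20% in spleen and 0.10% in both muscle libraries, 23.8% (20.5 to 27.2) and 23.0% (19.9 to 26.3) of muscle cells lay above the spleen median, and 18.5% (14.0 to 23.8) of spleen cells lay below either muscle median. At 1000 UMIs a share of 0.10% is 1 UMI, so the resting lymphoid medians sit near the floor, and the 18.5% ranged from 13.0% to 28.2% with other thinning depths.

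**Figure D3:**
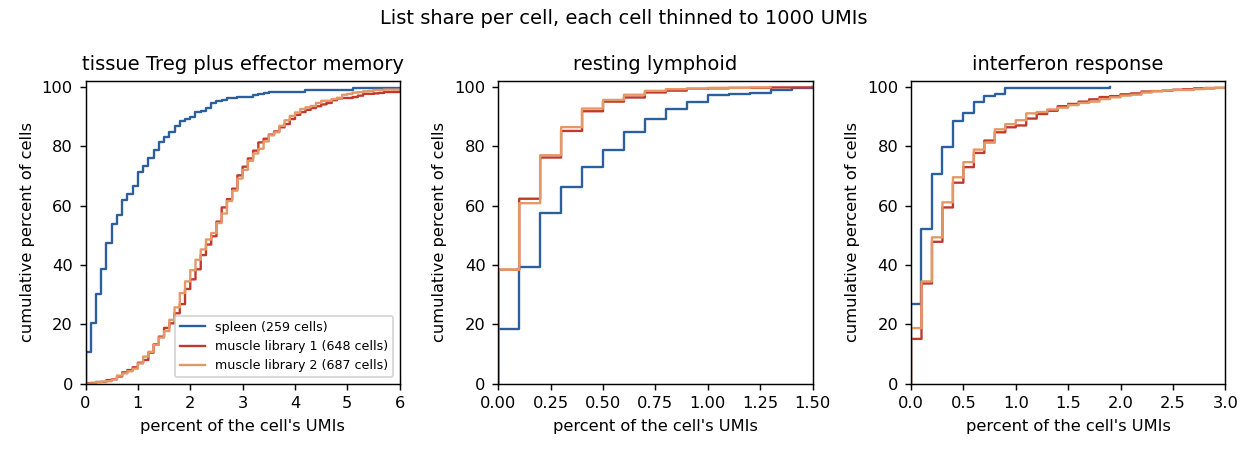
Cumulative percent of cells (vertical axis) by the percent of a cell's UMIs that falls on 3 fixed lists (horizontal axis), for 259 spleen cells, 648 cells of muscle library 1 and 687 cells of muscle library 2, each thinned to 1000 UMIs. The curves of the muscle libraries run together, and for tissue Treg plus effector memory genes they lie to the right of spleen, with medians of 2.50% and 2.40% against 0.50%.

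Clustering of all cells gave 7 groups, 4 of which could be named from the fixed markers. Cluster 1 was interferon-signature, with Ifit3, Ifit1, Usp18 and Rsad2 among its 10 leading genes, and held 17.1% (14.3 to 20.1) of the cells of muscle library 1 and 14.4% (11.9 to 17.2) of muscle library 2. Cluster 4 was led by immediate early genes, with Egr1, Fosb, Fos and Jun among its 10 leading genes. Such genes are part of the set named stress beforehand, whose heat shock genes were absent from the cluster's 50 leading genes. Cluster 4 held 18.8% (16 to 22.0) and 20.7% (17.8 to 24.0). Cluster 5 was resting Treg-like by Tcf7, Ccr7 and Bcl2, and held 3.86% (2.54 to 5.60) and 3.75% (2.46 to 5.44) of the muscle cells. Cluster 6, of only 20 cells over the 3 libraries, was cycling by Ccnb2, Ccna2, Birc5, Ube2c and Plk1, and held 1.19% (0.51 to 2.33) and 1.3% (0.59 to 2.45). Cluster 0, led by Penk, Dgat2 and Cd83, counted 9 tissue Treg genes among its 50 leading genes but 2 among its 10. It stayed unnamed and held 28.5% and 28.4%. Clusters 2 and 3, also unnamed, held 13.2% and 12.4%, and 17.4% and 19.0%. No cluster was led by genes of another cell type. In every cluster the share in each muscle library lay within the interval of the other, and spleen shares are not compared because genes that differ between the tissues define these clusters.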

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

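Against 569 genes higher and 263 lower in muscle, TMM factors gave 516 and 307, DESeq2 size factors 507 and 317, and totals without ribosomal protein genes 439 and 394. For named genes, 922 of the recomputed folds stayed within the spread of the muscle libraries and 215 moved beyond it. The 922 include settings that could not move a fold beyond that spread. These are the UMI minimum, which leaves folds unchanged, and each muscle library alone. Of the recomputed folds 20 changed sign, all in genes outside the 2-fold rule. For list counts and medians 429 stayed and 111 moved, and for shares of cells, which follow the depth kept per cell, 608 stayed and 625 moved. The clustering without genes called between tissues was chosen after seeing the data. No paired analysis was possible because the spleen has 1 library and the labels pair no samples. No cluster was led by another cell type, so the alternative without such clusters was not run.

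Counts moved with the thresholds, as fewer or more genes qualify by construction. With at least 10 UMIs, 987 genes were higher and 606 lower in muscle, and 887 higher and 549 lower in muscle library 2 than in library 1. With at least 200 UMIs the counts were 211 and 66, and 32 and 12. The 1.5-fold rule gave 1208 and 825, and 841 and 661, and the 3-fold rule 223 and 72, and 48 and 20. Equal weight per cell gave 642 genes higher and 326 lower in muscle. Cells thinned to 1000 UMIs gave 786 genes higher and 399 lower in muscle, and 428 higher and 325 lower in muscle library 2, where the added sampling noise was not separated. Without muscle replicate 1 or 2, 525 to 530 genes were lower in muscle, since a single library then decides. With at least 200 UMIs 7 tissue Treg genes were higher and 3 resting lymphoid genes lower.

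The share of spleen cells below the muscle median of resting lymphoid genes moved with depth: for muscle library 1 it was 28.2% at 750 UMIs, 13.0% at 1500 UMIs and 25.1% without thinning, and for muscle library 2 28.2%, 26.4% and 23.9%; single UMIs decide these medians. Leiden resolution 0.5 gave 4 clusters and resolution 1.2 gave 13. The cycling cluster of 20 cells did not recur at that size, since the smallest cluster of any alternative held 37 cells. Alternative clusters were matched to the named ones by shared cells, and their leading genes were not examined. At resolution 0.5 the best match of the resting Treg-like cluster held 8.75% and 9.80% of the 2 muscle libraries. The best match of the immediate early cluster held 43.3% and 44.4%, as clusters merged. At resolution 1.2 the latter match held 10.8% and 10.1%, and with 10 principal components 17.4% of muscle library 2. Without immediate early, heat shock and ribosomal protein genes the best match of the immediate early cluster held 27.4% and 31.8%. The best match of the resting Treg-like cluster then held 2.16% of muscle library 2, and the cause was not tested. Clustered without the genes called between tissues, 7 clusters formed and all held cells of every library, the largest spleen share being 37.8% (31.9 to 44.0) in a cluster with 18.1% and 21.8% of the muscle libraries. Depth limits genes with few spleen UMIs, whose folds have wide intervals.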

Other observations

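The following genes for secreted or cell surface factors were chosen after their values were seen, and such factors as a group were not tested. Penk, the precursor of enkephalin peptides, was 4.20-fold (3.02 to 5.95) higher in muscle library 1 and 4.77-fold (3.47 to 6.73) higher in muscle library 2 than in spleen. Il1rn, the interleukin 1 receptor antagonist, was 8.09-fold (3.95 to 19.2) and 6.09-fold (2.97 to 14.5) higher, and Metrnl, a secreted factor linked to tissue repair, 4.93-fold (2.76 to 9.58) and 4.77-fold (2.69 to 9.22) higher. Pdgfb, a growth factor for mesenchymal cells, had 1 spleen UMI against 24 and 22 in the muscle libraries, under the UMI minimum, and Bmp7 was 2.46-fold and 2.26-fold higher. Tnfsf8, the ligand of CD30 and a member of the conventional CD4 list under the UMI minimum, went the other way with 22 spleen UMIs against 2 in each muscle library.

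The tests on reads per UMI, on digestion of the muscle sample alone, on a minority of cells and on myeloid cells were chosen after results bearing on them had been seen; that on immediate early content was set before its result was seen.

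Genes higher in muscle library 2 than in muscle library 1 tracked sequencing depth per molecule. In the third of cells with the most reads per UMI, the 240 genes took a larger share of UMIs than in the third with the fewest. The log2 difference was 0.63 within muscle library 1, 0.51 within muscle library 2 and 0.41 within spleen. Spleen entered the choice of these genes only through the UMI minimum. The 136 genes lower in muscle library 2 showed no such trend, at -0.17, 0.03 and -0.06. Reads per UMI may therefore contribute to the first set, while other differences between the libraries' preparation stay open for both. For the tissue difference the same explanation is argued against: within the muscle libraries the genes higher in muscle differed by 0.01 and -0.0037, and the genes lower in muscle by -0.09 and -0.063, where depth as the cause would need a clear fall and a clear rise, since muscle cells have fewer reads per UMI. Within spleen the 2 sets differed by 0.31 and -0.16, so genes higher in muscle do track reads per UMI there, in the direction opposite to that need.

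Of 16 measured immediate early genes, 4 were higher and 1 lower in the digested muscle sample, with a list median log2 of 0.489, beside a heat shock list at -0.56. Digestion and tissue cannot be told apart for this list, because all muscle cells were digested and no spleen cells were. A digestion response that follows a cell's immediate early content is argued against for the summed share of the other genes higher in muscle, not gene by gene. Between the third of muscle cells richest in immediate early UMIs and the third poorest, the summed share of 565 such genes differed little. The log2 difference was 0.02 in muscle library 1 and 0.074 in muscle library 2. Single genes may still follow that content: Lmna was among the 10 leading genes of cluster 4, which immediate early genes led, and Vim among its 50. A digestion response equal in all cells stays open, as does the tissue itself.

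Interferon response genes formed their own muscle cluster, so a minority of muscle cells might have carried the tissue difference. The mean list share in muscle over spleen was 2.23 and 2.15 over all cells. After thinning, 27.0% of spleen cells held 0 UMIs of the list, against 15.1% and 18.8% of muscle cells, and 52.1% held at most 1, against 33.8% and 34.5%. If all other muscle cells were like spleen cells, at least 44.0% of the cells of muscle library 1 and 33.8% of muscle library 2 would have to differ, counting error aside. That is more than the 17.1% and 14.4% in the interferon cluster but less than most cells, so a minority of cells and a shift of most cells cannot be told apart. Myeloid cells in the sort, or doublets with them, are argued against. In the fifth of muscle cells richest in interferon genes, 15 myeloid genes, without Ctss and Cst3, took at most 6.65 CPM. Over all cells they took 27.4 CPM in muscle library 1 and 22.4 in muscle library 2. That low level bounded the value in the fifth, so the evidence there is the lack of enrichment. It rests on few UMIs, and doublets with other cell types were not tested. A response of muscle Tregs to interferon after injury is a candidate explanation that stays untested, along with the handling of the muscle sample.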
